A study of Mus musculus with 26 samples.

How the data were processed

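RNA sequencing of total RNA was done in 26 mouse libraries. Of these, 6 came from bone marrow-derived conventional type 1 dendritic cells (cDC1; 3 control and 3 Carm1-KO) and 20 from MSR scaffolds harvested at the vaccination site. Per the labels' protocols, RNA was extracted with Trizol and 500 ng of total RNA went into each library, which a commercial provider made and sequenced. Per the submitters' processing notes, STAR, SAMtools and DESeq2 were used with the mouse build mm10, with no versions or roles. The read counter, the gene annotation and the strand setting are not given in the sources used here, so a gene's reads cannot be told apart from those of an overlapping or antisense gene.

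For the cDC1 libraries the deposited values were raw read counts per gene, whole numbers with no normalization, for 35949 gene names. For the scaffolds the deposited values were normalized counts, a linear signal per gene. The values themselves show whole reads divided by 1 size factor per library, since 100% of them came out whole within 0.01, with size factors between 0.888 and 1.14. The scaffold table lists 17521 genes, all with at least 10 recovered reads in at least 5 libraries, so genes under that floor were not measured. Of the 20 scaffold libraries, 10 had a column each (6 control vaccine, 4 EZM2302 vaccine). The other 10 carry the same replicate numbers with the letter s, whose meaning the labels do not give, and were not analysed here. Whether their reads were added into the 10 columns is not stated. No column of the tables lacked a matching library.

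Total counts were 10567186, 8058687 and 8038757 in the 3 control and 6928333, 6076191 and 7463307 in the 3 Carm1-KO cDC1 libraries. Recovered reads were 12451394 to 14281390 per scaffold library. The 10 most abundant genes took between 10.0% and 11.2% of the cDC1 counts and between 7.12% and 9.06% of the scaffold reads. No replicates were near copies of one another, since the smallest chi-square per degree of freedom between any pair within a group was 5.03. Precision was tested on simulated data drawn from the real means and totals. For the cDC1 design, run on 12224 genes, 48 of 100 genes changed by 1.5-fold and 66 of 100 changed by 2-fold were recovered, and 9 of the 135 calls (6.67%) were unchanged genes. For the scaffold design, run on 17505 genes, 7 of 100 genes changed by 1.5-fold and 48 of 100 changed by 2-fold were recovered, with 0 unchanged genes among 57 calls by limma and 2 among 59 by edgeR on the reads. A simulated set of 20 genes changed by 1.4-fold was called in both designs, and 0 of 100 unchanged sets were called by camera. Genes were simulated independently, so this does not show how camera with a preset correlation performs on lists of correlated genes.

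The comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined. Carm1-KO and control cDC1 counts were compared in R 4.3.3 with edgeR 4.0.16, using TMM factors, filterByExpr and the quasi-likelihood F test, which was two-sided. CPM values are scaled with TMM. Scaffold values were compared with limma 3.58.1 (eBayes with trend, two-sided) on log2(normalized count + 1) for genes with at least 10 normalized counts in at least 4 libraries, so that the fold change of genes with low values is understated. The plan had been to average each plain library with its s library, and each plain library stood alone here. Benjamini-Hochberg adjusted p under 0.05 was the threshold in both. Gene lists (38 in all, for pathways and cell types) with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, 26 lists in cDC1 and 37 in scaffolds. The same lists were tested with an estimated correlation and with fry, and members were also adjusted over the list alone. Gene sets that changed in Carm1-KO cDC1 were tested with camera in the scaffolds. All genes were compared without a block for the replicate number.

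Named genes were Carm1 and the other Prmt genes. They were also the 10 highest and 10 lowest log2 fold changes among called genes whose groups did not overlap, with a mean of at least 2 CPM or 20 normalized counts and an official name. From each list came up to 4 called members or, with none called, up to 2 of the smallest p. Genes named outside this rule are said to be so, and 2 genes that the rule names are not reported here. Coordinates and exons come from GENCODE M21 on GRCm38, the assembly that mm10 denotes, with positions counted from 1. Of the gene names, 26737 in the cDC1 table and 17145 in the scaffold table were found there, covering 11278 of 12224 and 17117 of 17492 tested genes.

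The alternatives fixed beforehand for cDC1 were RLE size factors, DESeq2 1.42.0, limma-voom, no filter, a stricter filter, the replicate number as a block and each library left out. For the scaffolds they were pseudocounts of 0.5 and 10, no filter, quantile normalization, median centring, edgeR on the recovered reads, the block and each library left out. Alternatives added after seeing the data were thinning to the smallest total and a length correction in cDC1. For the scaffolds they were leaving out the libraries with the highest adipocyte or globin levels, either level as a covariate and, for lists, each library left out and quantile normalization. The estimated correlation was also applied, after seeing the data, to the lists called without a library in either comparison, with the globin level as a covariate, and without the fat-rich or globin-rich libraries. The alternatives and the comparison that needed the s libraries were not run.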

Results

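Gene expression was measured in 2 mouse settings. In the first, conventional type 1 dendritic cells (cDC1) were grown from bone marrow, with 3 control and 3 Carm1-KO libraries. These dendritic cells present antigens taken up from other cells to CD8 T cells. Carm1 encodes an arginine methyltransferase that modifies histones and other proteins, and the comparison asks which transcripts differ without the gene. In the second, MSR scaffolds were recovered from the vaccination site of mice given a control vaccine (6 libraries) or a vaccine with EZM2302 (4 libraries), a small-molecule inhibitor of CARM1. Total counts per cDC1 library were 10567186, 8058687 and 8038757 in the controls and lower in all 3 Carm1-KO libraries (6928333, 6076191 and 7463307). Recovered reads per scaffold library ran from 12451394 to 14281390. The labels call the replicates biological without naming animals or cultures, so p-values measure the spread between these libraries.

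Carm1, the targeted gene, lies on chromosome 9 from 21546894 to 21592623 on the plus strand of mm10. It was at 39.8, 51.4 and 45.7 CPM in the control cDC1 libraries and at 37.0, 30.7 and 33.5 CPM in the Carm1-KO libraries, each of which lay below each control. The means were 45.7 ± 5.81 and 33.7 ± 3.15 CPM (SD, n = 3 each). The log2 fold change was -0.43 (SE 0.14) with edgeR's quasi-likelihood adjusted p = 0.131, so Carm1 did not pass the threshold over all genes. The labels do not say how the gene was knocked out or which part, if any, was deleted. A count over the whole gene would also hold reads from any part that remains. Among the 8 arginine methyltransferase genes measured, Carm1 was the 1 that was lower when adjusted over the list alone, while edgeR and DESeq2 called 0 over all genes (3 at an unadjusted p under 0.05; median 0.09, camera adjusted p = 0.3996). The edgeR log2 fold changes of Prmt6 (0.25, adjusted p = 0.268), Prmt7 (0.51, adjusted p = 0.333), Prmt2 (0.51, adjusted p = 0.462) and Prmt1 (0.14, adjusted p = 0.698) did not pass.

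Carm1-KO cDC1 had less Xcr1 and Ccl5 and more Tlr12 than control cDC1. Xcr1, the XCL1 receptor that marks this cell type (chromosome 9, 123852315 to 123862029), fell from 867 ± 128 to 519 ± 27.5 CPM (SD, n = 3 each), a log2 fold change of -0.74 (SE 0.10, edgeR adjusted p = 0.000596). Ccl5, a chemokine for T cells, fell from 168 ± 19.1 to 108 ± 6.14 CPM (log2 -0.63, SE 0.10, edgeR adjusted p = 0.00296). Tlr12, which senses profilin of protozoan parasites (chromosome 4, 128615443 to 128618619), rose from 193 ± 8.50 to 275 ± 15.6 CPM (log2 0.51, SE 0.09, edgeR adjusted p = 0.00552). Tyrobp, the signalling adaptor of several myeloid and NK cell receptors, fell from 120 ± 40.5 to 59.7 ± 5.91 CPM (log2 -1.01, SE 0.17, edgeR adjusted p = 0.00703).

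Among called genes of official name, with groups that did not overlap and a mean of at least 2 CPM, the highest changes reported ran from 0.91 to 1.32 on the log2 scale. They belonged to Gdap10, Orm3 (an acute-phase protein), Dnajc28, Mab21l3, Snord96a, Pfdn6 (a prefoldin chaperone subunit), Ppp1r14a (an inhibitor of myosin phosphatase), Tsix and Ruvbl1 (an ATPase of chromatin remodelling complexes). Pfdn6 rose from 24.3 ± 4.14 to 46.6 ± 3.94 CPM (log2 0.95, SE 0.15, edgeR adjusted p = 0.00296). The 10 lowest ran from -1.05 to -0.88 and belonged to Hpgd (which breaks down prostaglandins), the mitochondrial ATP synthase gene ATP8, Mir682, Tyrobp, Frg1, Cand2, Zfp358, the histone genes Hist1h2ap and Hist1h2ao, and Cox6c (a subunit of cytochrome c oxidase). Hpgd fell from 26.7 ± 9.08 to 13.0 ± 3.71 CPM (log2 -1.05, SE 0.24, edgeR adjusted p = 0.0325) and Cox6c fell to 0.544-fold (log2 -0.88, SE 0.17, edgeR adjusted p = 0.0145). The smallest p of all belonged to Zfp366, a transcription factor of dendritic cells, named here after its values were seen, which rose from 94.9 ± 6.08 to 168 ± 12.2 CPM (log2 0.82, SE 0.10, edgeR adjusted p = 0.000309). Of the 34 named and called genes with an annotation, 16 shared exonic bases with another gene, and their values are uncertain. They were Snord96a, Pfdn6, Tsix, Mir682, Cand2, Hist1h2ap, Hist1h2ao, Cox6c, Ifi203, Bax, Hexa, Pdia6, Zfp36, S100a4, Spp1 and Klrb1b. Tsix is antisense to Xist (log2 0.15, edgeR adjusted p = 0.375). Cand2 overlaps Rpl32 on the other strand (log2 -0.68, edgeR adjusted p = 0.0293). Snord96a shares bases with Rack1 and Mir682 with a gene model, and the histone copies are near-identical.

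The dendritic cell lists moved in parts. Of 24 cDC1 identity genes measured, 1 was higher (Tlr12) and 1 lower (Xcr1), or 5 and 4 adjusted over the list alone, with a median log2 fold change of 0.01 (camera adjusted p = 0.416). The MHC class I presentation list ranked higher (23 measured, 17 of them positive, median 0.12, camera adjusted p = 0.00964, but adjusted p = 0.583 with an estimated correlation). In that list, 1 gene was higher over all genes and 6 higher and 2 lower adjusted over the list alone. The called gene was H2-Q6, which rose from 69.9 ± 23.3 to 109 ± 7.64 CPM (log2 0.65, edgeR adjusted p = 0.0379) and whose reads are hard to separate from those of its paralog H2-Q7. Neither MHC class II presentation (14 genes, median -0.06, camera adjusted p = 0.303) nor cross-presentation machinery (25 genes, median 0.12, camera adjusted p = 0.216) passed. In the class II list, edgeR called 0 over all genes (6 at an unadjusted p under 0.05, 1 by DESeq2), and 2 were higher and 3 lower adjusted over the list alone. In the cross-presentation list, edgeR called 0 (9 at an unadjusted p under 0.05, 4 by DESeq2), with 3 higher and 2 lower adjusted over the list alone. Values of their members of smallest p were H2-Oa -0.56 (edgeR adjusted p = 0.0523), Cd74 -0.29 (0.130), Rac2 -0.50 (0.0505) and Cyba 0.39 (0.0648). The maturation list had Ccl5 as its 1 called member of 29 (1 higher and 2 lower adjusted over the list alone). Its median was 0.01 and its mean -0.03, and camera ranked it lower (adjusted p = 0.532), so the signs differ.

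Markers of neighbouring cell types ranked lower in Carm1-KO. The list of cDC2 and monocyte-derived dendritic cell markers had 7 of 8 measured genes negative (median -0.30, camera adjusted p = 0.00109, but adjusted p = 0.524 with an estimated correlation), with 1 lower over all genes and 2 lower adjusted over the list alone. S100a4 of this list, a calcium-binding protein, fell from 169 ± 23.7 to 113 ± 17.9 CPM (log2 -0.58, edgeR adjusted p = 0.0189). In the list of NK and innate lymphoid markers all 6 measured genes were negative (median -0.60, camera adjusted p = 0.0188, but adjusted p = 0.524 with an estimated correlation), with 1 lower over all genes (Klrb1b, log2 -0.58, edgeR adjusted p = 0.0258) and 2 adjusted over the list alone. Among 9 plasmacytoid dendritic cell markers, Spib, a transcription factor of that lineage and of B cells, fell from 32.9 ± 9.62 to 17.9 ± 2.57 CPM (log2 -0.87, edgeR adjusted p = 0.0321), while the list as such did not pass (median -0.16, camera adjusted p = 0.216). Neither did monocyte and macrophage markers (14 genes, median -0.08, camera adjusted p = 0.380) or markers of alternatively activated macrophages (5 genes, median -0.00, camera adjusted p = 0.318). Of the latter list, Spp1, the secreted protein osteopontin, fell from 75.3 ± 13.7 to 48.8 ± 12.6 CPM (log2 -0.63, edgeR adjusted p = 0.0492), with groups that overlapped and exonic bases shared with another gene model.

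Of the metabolic and stress lists, glycolysis and hypoxia ranked higher (18 of 25 positive, median 0.20, camera adjusted p = 0.00964, but adjusted p = 0.524 with an estimated correlation). Its 1 called gene, also the only 1 adjusted over the list alone, was the glycolytic enzyme Pgk1, which rose from 49.1 ± 9.82 to 72.5 ± 5.79 CPM (log2 0.56, edgeR adjusted p = 0.0360). Called single members of lists that did not pass were Bax, the apoptosis effector (log2 0.52, edgeR adjusted p = 0.0348), Hexa of the lysosome list (0.36, 0.0423), Pdia6 of the unfolded protein list (0.46, 0.0343) and Ifi203 of the type I interferon list (-0.41, 0.0379). The immediate early genes Zfp36 and Nr4a1 fell by 0.45 (edgeR adjusted p = 0.0183) and 1.13 (0.0383), with overlapping groups for Nr4a1. With a library left out, the log2 fold change of Nr4a1 ran from -1.43 to -0.48, and it passed in 2 of 6 such fits. The immediate early list had a median of 0.02 and a mean of -0.09, with camera lower (adjusted p = 0.532), so the signs differ. The NF-kB list (27 genes, median 0.10, camera adjusted p = 0.216) was called higher without control 1 (0.0109) or Carm1-KO 2 (0.0136). The unfolded protein list (27 genes, median 0.07, camera adjusted p = 0.178) was called higher without the same 2 libraries (0.0397 and 0.0299). The type I interferon list (45 genes, median 0.06, camera adjusted p = 0.3996) was called higher without Carm1-KO 3 (0.0134) and MHC class II presentation lower without control 3 (0.0104). None of these calls held with an estimated correlation, where the smallest adjusted p of any list called by camera without a library was 0.441. Interferon-gamma-induced genes (18 genes, median 0.14, camera adjusted p = 0.342), cholesterol synthesis (23 genes, median 0.11, 0.188), p53 targets (20 genes, median 0.05, 0.3996), lysosome genes (33 genes, median -0.04, 0.889) and proliferation genes (36 genes, median 0.06, 0.532) did not pass.

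**Figure D1:**
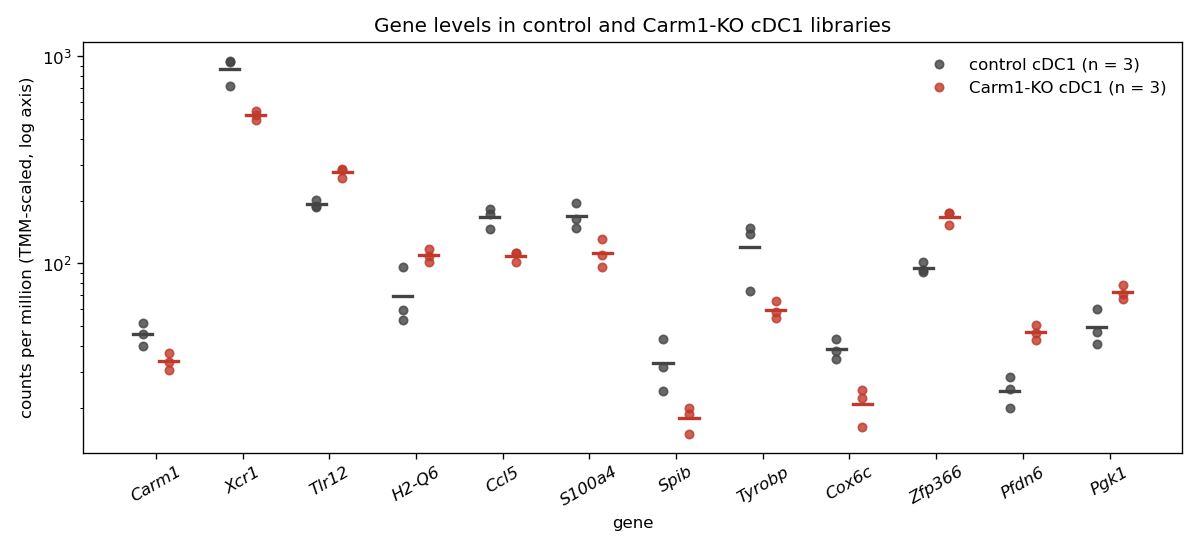
Levels of 12 genes in 3 control and 3 Carm1-KO cDC1 libraries, in TMM-scaled CPM on a log axis. Each point is a library and each bar a group mean. Carm1 was lower in all 3 Carm1-KO libraries without passing the threshold, Xcr1 fell from a mean of 867 to 519 CPM and Tlr12 rose from 193 to 275 CPM.

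In all, edgeR's quasi-likelihood test called 85 genes higher and 69 lower in Carm1-KO among 12224 tested, with 1789 at an unadjusted p under 0.05. Of the 154, 12 rose and 5 fell by over 2-fold, the median absolute log2 fold change was 0.58, and 151 had groups that did not overlap. Such separation held for 19.2% of all tested genes, where chance gives 10%. The number of calls hung on single libraries: it was 46, 17 and 580 without control 1, 2 and 3, and 21, 23 and 13 without Carm1-KO 1, 2 and 3. Of 35 named and called genes, 4 (Mir682, Hist1h2ao, Xcr1 and Ccl5) passed in all 6 of these fits, and the MHC class I list lost its call without Carm1-KO 1 (camera adjusted p = 0.0668).

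The scaffold comparison asks which transcripts at the vaccination site differ when the vaccine holds the CARM1 inhibitor. Carm1 itself was at 356, 439, 453, 397, 354 and 388 normalized counts in the control vaccine libraries and at 347, 501, 400 and 408 in the EZM2302 libraries (398 ± 41.2 against 414 ± 63.9, SD, n = 6 and 4). Its log2 fold change was 0.05 (SE 0.12, limma adjusted p = 0.875). Among the 8 Prmt genes measured, Prmt2 (0.38, limma adjusted p = 0.214) and Prmt6 (-0.27, 0.337) had the smallest p, and the list did not pass (median 0.03, camera adjusted p = 0.933).

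EZM2302 scaffolds had more Tnc, Cxcl1, Cxcl5 and Pou2af1 and less Tlr9 than control vaccine scaffolds. Tnc, the matrix protein tenascin C, rose from 2512 ± 886 to 12054 ± 3842 normalized counts (SD, n = 6 and 4), a log2 fold change of 2.29 (SE 0.28, limma adjusted p = 0.0115). Cxcl1 and Cxcl5, ligands of the neutrophil receptor CXCR2, rose from 78.0 ± 31.7 to 479 ± 240 (log2 2.46, SE 0.43, limma adjusted p = 0.0296) and from 506 ± 166 to 2214 ± 702 (log2 2.15, SE 0.33, limma adjusted p = 0.0220). Pou2af1, a coactivator of B cells, rose from 15.8 ± 13.3 to 121 ± 36.3 (log2 3.20, SE 0.56, limma adjusted p = 0.0296). Tlr9, the endosomal sensor of unmethylated DNA, fell from 1762 ± 219 to 911 ± 155 (log2 -0.96, SE 0.13, limma adjusted p = 0.0158).

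The highest and lowest changes were taken among called genes of official name, with groups that did not overlap and a mean of at least 20 normalized counts. The other genes among the 10 highest were the antibody light chain segments Igkv1-110, Igkv1-117 and Igkv14-126 (log2 4.45, 3.81 and 3.14), Retnlg (a neutrophil resistin-like protein, 2.28), Tenm3 (2.22) and Il13ra2 (the decoy receptor of IL-13, 2.16), with limma adjusted p from 0.0124 to 0.0414. Igkv segments belong to a family of near-identical genes, so the reads of each are uncertain. Within these limits the 10 lowest ran from -1.20 to -0.83 on the log2 scale. Besides Tlr9 they were Bex6, Map4k1 (a kinase downstream of antigen receptors), Sh2d1b1, Slc52a3, Aldh1b1, Fkbp5 (a glucocorticoid-induced chaperone), Sla (an adaptor that dampens antigen receptor signalling), Sirpb1a and Slc28a2. Map4k1 fell from 457 ± 46.3 to 213 ± 63.2 (SE 0.18, limma adjusted p = 0.0226) and Sla from 1951 ± 104 to 1082 ± 178 (SE 0.11, limma adjusted p = 0.0129). Of the 33 named and called scaffold genes, 6 shared exonic bases with another gene and are uncertain: Tnc, Tenm3, Ciita, Il4i1, Mmp12 and Lox.

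Fibroblast and matrix genes ranked higher in EZM2302 scaffolds, with 24 of 25 positive (median 0.65, camera adjusted p = 2.17e-07, but adjusted p = 0.697 with an estimated correlation). In this list 3 genes were higher over all genes and 8 adjusted over the list alone. Cxcl12, a stromal chemokine, rose from 1756 ± 351 to 4005 ± 390 (log2 1.21, SE 0.15, limma adjusted p = 0.0115), Lox, which crosslinks collagen, rose from 4666 ± 1076 to 12488 ± 3848 (a fold of 2.64, limma adjusted p = 0.0273), and Col5a2 rose by 0.90 (0.0402). Endothelial markers had 14 of 17 positive (median 0.39, camera adjusted p = 0.0216, but adjusted p = 0.781 with an estimated correlation), with 0 called by limma and by edgeR on the reads (2 at an unadjusted p under 0.05). This call was lost without control 3 (camera adjusted p = 0.0602) or EZM2302 3 (0.135).

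Neutrophil markers and inflammatory cytokines ranked higher too. Of 21 neutrophil markers, 19 were positive (median 1.10, camera adjusted p = 2.72e-07, but adjusted p = 0.697 with an estimated correlation), with 1 higher over all genes (Retnlg, from 891 ± 479 to 4290 ± 2165) and 12 adjusted over the list alone. The mean log2 level of these markers was 9.55 and 8.43 in EZM2302 libraries 1 and 2, and 7.09 to 9.18 in the controls. Of 33 NF-kB and cytokine genes, 28 were positive (median 0.40, camera adjusted p = 1.06e-05, but adjusted p = 0.781 with an estimated correlation), with 1 higher (Cxcl1) and 3 adjusted over the list alone. Glycolysis and hypoxia genes were positive in 27 of 28 cases (median 0.28, camera adjusted p = 0.000540, but adjusted p = 0.821 with an estimated correlation and 0.0612 by camera without EZM2302 1). Vegfa, the angiogenic growth factor and the 1 higher gene there by either adjustment, rose from 1422 ± 291 to 3876 ± 1088 (log2 1.42, SE 0.20, limma adjusted p = 0.0173).

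B cell and plasma cell markers were positive in 16 of 16 cases (median 1.38, camera adjusted p = 9.51e-07, but adjusted p = 0.416 with an estimated correlation), with 0 called over all genes by limma and by edgeR on the reads (8 at an unadjusted p under 0.05) and 8 higher adjusted over the list alone. Igkc and Ighm, the kappa and mu constant regions, had log2 values of 3.22 (limma adjusted p = 0.0588) and 2.42 (0.0632). The list's mean log2 level was 7.13, 7.004, 7.90 and 7.50 in EZM2302 libraries 1 to 4 and 5.15 to 6.54 in the controls. Erythroid and platelet markers were positive in 8 of 9 cases (median 2.36, camera adjusted p = 0.00150, but adjusted p = 0.622 with an estimated correlation), with 4 higher adjusted over the list alone, while limma called 0 over all genes (5 at an unadjusted p under 0.05, 4 by edgeR on the reads). Hbb-bs, a beta globin whose paralog Hbb-bt shares its reads, went from 893 ± 250 to 7661 ± 7133 (log2 2.41, limma adjusted p = 0.0825). The 4 globin genes averaged 13.1 and 12.9 on the log2 scale in EZM2302 libraries 3 and 4, 9.56 and 9.46 in libraries 1 and 2, and 7.96 to 9.53 in the controls. With the globin level as a covariate, the median of the B cell list was 0.23 (camera adjusted p = 0.0621), that of the neutrophil list 0.84 (0.00182) and the NF-kB list, at 0.21, lost its call (0.0528), while the neutrophil call was lost as well with an estimated correlation (adjusted p = 0.673). Without EZM2302 libraries 3 and 4 the medians of these 3 lists fell to 0.21, 0.83 and 0.18 (camera adjusted p = 0.0299, 0.000363 and 0.0333, but adjusted p = 0.752, 0.796 and 0.840 with an estimated correlation).

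MHC class II presentation ranked lower, with 10 of 13 negative (median -0.38, camera adjusted p = 0.000906, but adjusted p = 0.622 with an estimated correlation), 2 lower over all genes and 7 adjusted over the list alone. Ciita, the transactivator of these genes, fell from 1682 ± 173 to 1123 ± 203 (log2 -0.59, limma adjusted p = 0.0424), and H2-DMb1, which helps load the peptide, fell from 1343 ± 158 to 901 ± 76.6 (log2 -0.57, limma adjusted p = 0.0323). MHC class I presentation ranked lower with a median of -0.17 and 19 of 23 negative (camera adjusted p = 0.0361, but adjusted p = 0.821 with an estimated correlation). That call was lost without control 2 (camera adjusted p = 0.0727), control 5 (0.0535), EZM2302 1 (0.357) or EZM2302 2 (0.624). The mean log2 level of this list was 11.81 in EZM2302 3, above all controls (11.401 to 11.602), and 11.11 to 11.394 in the other 3, below all of them. Its median was -0.32 without the 2 globin-rich libraries and -0.44 with the globin covariate (camera adjusted p = 1.39e-12 and 2.39e-13, but adjusted p = 0.138 and 0.415 with an estimated correlation). Without EZM2302 3 alone it was lower too (camera adjusted p = 3.86e-07, but adjusted p = 0.669 with an estimated correlation). Dendritic cell maturation genes ranked higher, with 24 of 32 positive (median 0.23, camera adjusted p = 0.00155, but adjusted p = 0.622 with an estimated correlation), 2 higher over all genes, and 6 higher and 1 lower adjusted over the list alone. Without EZM2302 3 this list did not pass (camera adjusted p = 0.0805). It did not pass by camera without the 2 globin-rich libraries or with the globin covariate either, with a median of 0.07 in each. Ccl22, a chemokine of mature dendritic cells, rose from 64.2 ± 10.7 to 198 ± 69.1 (log2 1.57, SE 0.22, limma adjusted p = 0.0158), and Il4i1 rose from 22.5 ± 4.28 to 54.3 ± 7.71 (log2 1.25, limma adjusted p = 0.0242). Of 24 cDC1 identity genes, Rab7b and Naaa fell by 0.71 (limma adjusted p = 0.0414) and 0.77 (0.0439), and 3 were lower adjusted over the list alone. The median of that list was 0.20 and its mean 0.06, while camera ranked it lower (adjusted p = 0.933), so the signs differ. With the globin covariate its median was -0.19 (camera adjusted p = 0.0353, but adjusted p = 0.450 with an estimated correlation). Cross-presentation machinery had a median of -0.04 (camera adjusted p = 0.291) and 3 lower adjusted over the list alone, with Wdfy4 at -0.58 (limma adjusted p = 0.0637).

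Of 50 type I interferon response genes, 42 were negative (median -0.23, camera adjusted p = 0.000118, but adjusted p = 0.821 with an estimated correlation), while limma and edgeR on the reads called 0 of them (9 at an unadjusted p under 0.05). Phf11d of this list was at -0.71 (limma adjusted p = 0.106), and the call was lost without EZM2302 2 (camera adjusted p = 0.346). The EZM2302 libraries differed, with a mean log2 level of 11.89 in library 3, above all controls (11.06 to 11.58), 11.21 in library 4, and 10.85 and 10.58 in libraries 1 and 2, below all of them. Without library 3 camera gave an adjusted p = 1.10e-18 (but adjusted p = 0.669 with an estimated correlation). The list's median was -0.64 without the 2 globin-rich libraries and -0.71 with the globin covariate (camera adjusted p = 2.40e-35 and 8.57e-26, but adjusted p = 0.479 and 0.450 with an estimated correlation), where 33 genes had an unadjusted p under 0.05 and limma called 0. CD8 and cytotoxic genes had 16 of 19 negative (median -0.28, camera adjusted p = 0.0376, but adjusted p = 0.821 with an estimated correlation). That call was lost without control 2 (camera adjusted p = 0.166), control 5 (0.289), EZM2302 1 (0.226), EZM2302 2 (0.186) or EZM2302 4 (0.289). Its median was -0.49 without the globin-rich libraries and -0.79 with the globin covariate (camera adjusted p = 0.000337 and 2.37e-06, but adjusted p = 0.796 and 0.6004 with an estimated correlation). Interferon-gamma-induced genes (24 genes, median -0.20, camera adjusted p = 0.278) were lower with the globin level as a covariate (median -1.03, camera adjusted p = 4.81e-17), as were T cell markers (-1.396, 3.16e-06), but neither passed with an estimated correlation, where the smallest adjusted p of any list called by camera in that fit was 0.415. T cell markers (median -0.32, camera adjusted p = 0.419), CD4 and regulatory T cell genes (median 0.31, 0.483) and NK and innate lymphoid markers (median -0.15, 0.965) did not pass without it. Without the globin-rich libraries the medians of interferon-gamma-induced genes and T cell markers were -0.76 and -0.79, in that order (camera adjusted p = 1.39e-12 and 0.00197, but adjusted p = 0.538 and 0.796 with an estimated correlation). Interferon-gamma-induced genes were also lower without EZM2302 3 (camera adjusted p = 3.07e-06) and T cell markers without control 1 (0.0458) or EZM2302 3 (0.00123), and no such call held with an estimated correlation (smallest adjusted p = 0.285 of any list called by camera without a library). T cell activation genes had a median of -0.24 and a mean of 0.06, with camera higher (adjusted p = 0.933), so the signs differ. Cholesterol synthesis genes were negative in 21 of 23 cases (median -0.34, camera adjusted p = 0.000360, but adjusted p = 0.781 with an estimated correlation), with 1 lower adjusted over the list alone.

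Other list shifts upward were those of immediate early genes (median 0.25, camera adjusted p = 0.0107, but adjusted p = 0.781 with an estimated correlation), unfolded protein response (median 0.12, 0.0216, and adjusted p = 0.781 with an estimated correlation), lymphocyte-recruiting chemokines (median 0.25, 0.0235, and adjusted p = 0.622 with an estimated correlation) and mitochondrially encoded genes (median 0.23, 0.0236, and adjusted p = 0.821 with an estimated correlation). Egr1, an immediate early transcription factor, rose by 1.08 (limma adjusted p = 0.0252). Without EZM2302 3 all 4 lost their calls (camera adjusted p = 0.134, 0.135, 0.304 and 0.390). The unfolded protein list also lost its call without control 2 (0.0694) or EZM2302 1 (0.0593), and the mitochondrial list without control 4 (0.0904), control 6 (0.0664) or EZM2302 2 (0.275). Adipocyte markers were negative in 12 of 12 cases (median -0.64, camera adjusted p = 0.173), and their mean log2 level was highest in control libraries 2 and 5 (10.9 and 10.4, against 4.99 to 8.91 in the other 8 libraries). Without those 2 libraries the immediate early, unfolded protein, glycolysis, MHC class I and cytotoxic lists lost their calls (camera adjusted p = 0.144, 0.108, 0.689, 0.145 and 0.820). Cross-presentation machinery was called lower in that fit (camera adjusted p = 0.0317, but adjusted p = 0.708 with an estimated correlation). Markers of monocytes and macrophages had a median of -0.02 and a mean of 0.09, and those of cDC2 and monocyte-derived dendritic cells a median of -0.09 and a mean of 0.09. Both were ranked lower by camera without passing, so the signs differ. Alternatively activated macrophage markers (median 0.25, camera adjusted p = 0.0729), p53 targets (median 0.15, 0.0911), proliferation genes (median -0.05, 0.483), lysosome genes (median 0.01, 0.628), and eosinophil (0.22, 0.278), mast cell (0.26, 0.628), keratinocyte (-0.04, 0.934), plasmacytoid dendritic cell (0.28, 0.420) and skeletal muscle markers (-0.52, 0.565) did not pass. Some of these were called without a library. Alternatively activated macrophage markers were higher without control 1, 3, 4 or 6 or EZM2302 3 (camera adjusted p = 0.0453, 0.0348, 0.0297, 0.0422 and 0.0337), and p53 targets without control 1 or EZM2302 1 (0.0458 and 0.0296). Adipocyte markers were lower without control 1 or 6 or EZM2302 3 (0.0320, 0.0338 and 0.0337), proliferation genes without EZM2302 2 (0.0168) and muscle markers without EZM2302 4 (0.0246). None of these calls held with an estimated correlation (smallest adjusted p = 0.285 of any list called by camera without a library). With the globin covariate, alternatively activated macrophage markers had a median of 0.98 (camera adjusted p = 0.00114, but adjusted p = 0.450 with an estimated correlation). Without the globin-rich libraries it was 0.66 (0.0303, but 0.796). Adipocyte markers had a median of -2.21 with that covariate (0.00203, but 0.673). The macrophage protease Mmp12 rose by 1.42 (limma adjusted p = 0.0499) and the T cell costimulator Tnfrsf9 by 1.35 (0.0439).

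**Figure D2:**
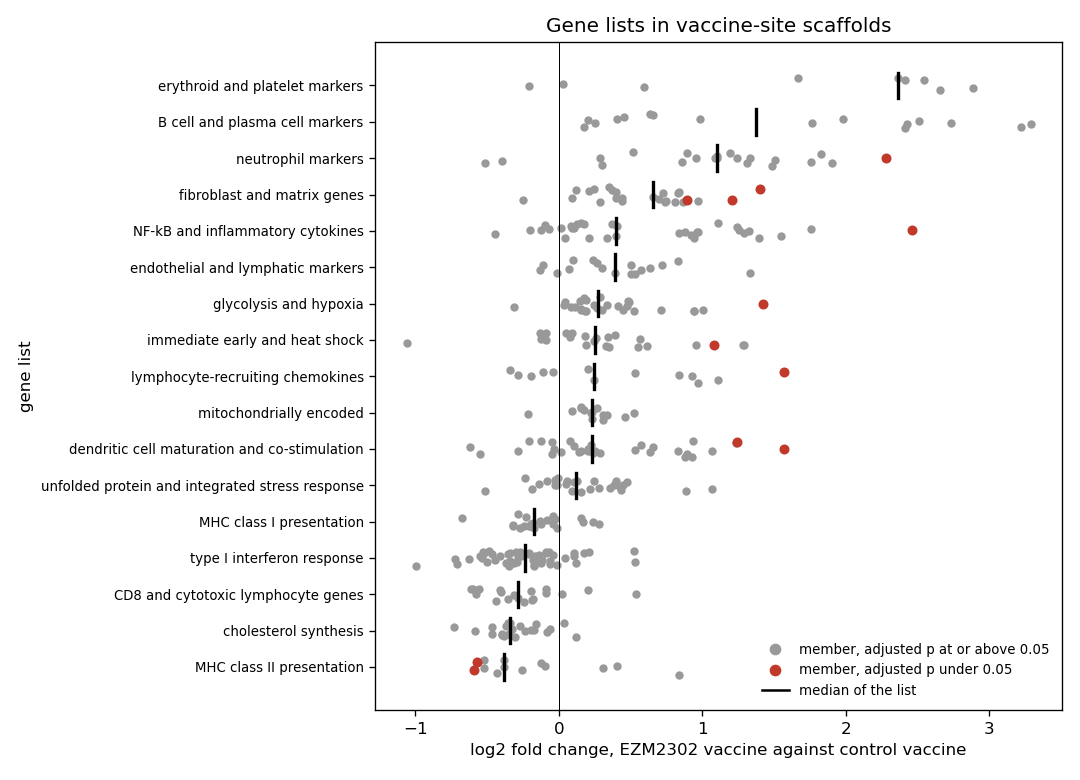
Log2 fold changes, EZM2302 against control vaccine, of the measured members of the 17 gene lists that passed camera in the scaffolds. Each point is a gene, red where the limma adjusted p was under 0.05, and each bar is the list median. Medians ran from -0.38 for MHC class II presentation to 2.36 for erythroid and platelet markers, and no list passed with an estimated correlation.

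**Figure D3:**
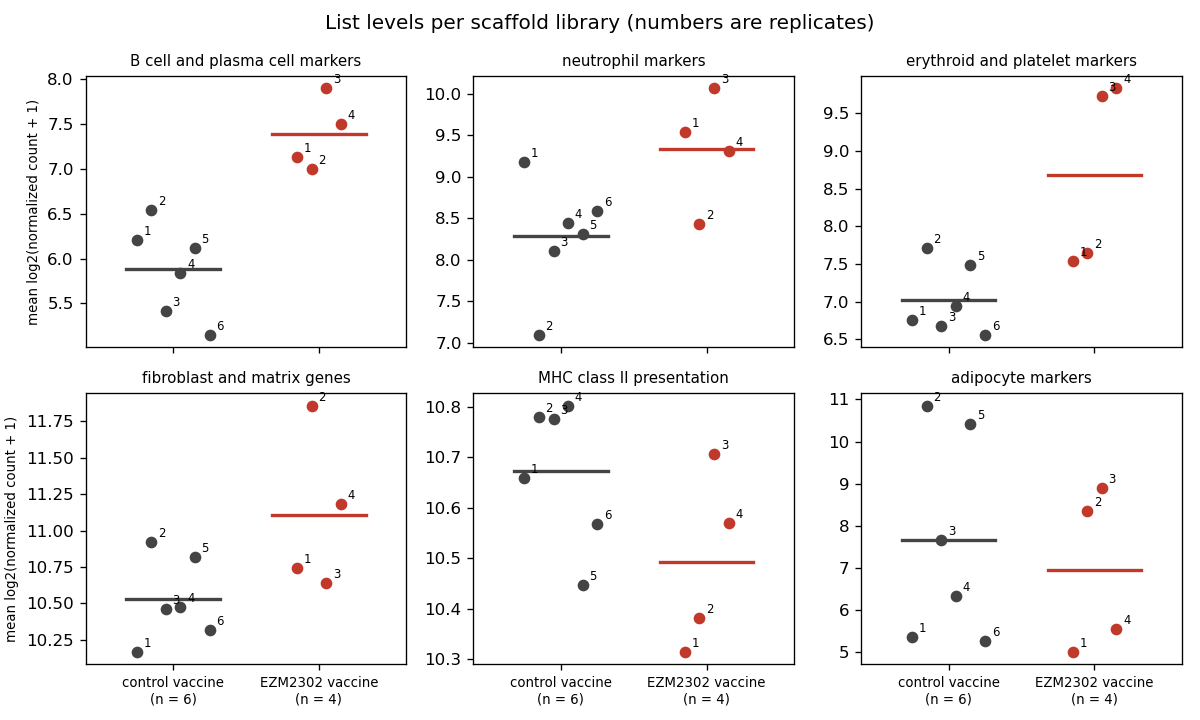
Mean log2(normalized count + 1) of 6 gene lists in each scaffold library, with 6 control and 4 EZM2302 libraries numbered by replicate and bars for group means. EZM2302 libraries 3 and 4 stood apart for erythroid and platelet markers, and control libraries 2 and 5 had the highest adipocyte levels. B cell levels in all 4 EZM2302 libraries lay above the highest control, 6.54.

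In all, limma called 165 genes higher and 99 lower among 17492 tested, with 3052 at an unadjusted p under 0.05. Of the 264, 107 rose and 8 fell by over 2-fold, the median absolute log2 fold change was 0.89, and 255 had groups that did not overlap, as did 4.91% of all tested genes where chance gives 0.952%. The number of calls was 101, 171, 29, 18, 251 and 51 without control 1 to 6 in turn, 38, 307, 637 and 13 without EZM2302 1 to 4, 441 without the 2 fat-rich controls, 125 without the 2 globin-rich EZM2302 libraries and 0 by limma with the globin level as a covariate (1804 at an unadjusted p under 0.05). Of 33 named and called genes 6 (Tnc, Il13ra2, Tlr9, Sla, Ccl22 and Cxcl12) passed in all 10 fits without a library, and 7 of the 17 called lists (B cell, MHC class II, NF-kB, cholesterol, erythroid, fibroblast and neutrophil) did too by camera, while none of these list calls held with an estimated correlation (smallest adjusted p = 0.285 of any list called by camera in these fits).

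Genes that differed between Carm1-KO and control cDC1 were then followed in the scaffolds, to ask whether the inhibitor moves them the same way. Of the 85 genes that rose in Carm1-KO, 63 were measured in scaffolds, with a median log2 fold change of -0.09 (20 positive, 43 negative, camera adjusted p = 0.158, and adjusted p = 0.365 with an estimated correlation). Of the 69 that fell, 55 were measured, with a median of -0.02 (27 positive, 28 negative, camera adjusted p = 0.735, and 0.824 with an estimated correlation). Among 10358 genes tested in both, calls shared were Trpm2, higher in both (0.377 by chance), and Cyp4f16 and Map4k1, higher in Carm1-KO and lower with EZM2302 (0.487 by chance). Of the 55 genes called lower in Carm1-KO by edgeR and tested in both, limma called 0 higher (0.329 by chance) and 0 lower (0.425 by chance). DESeq2 with edgeR on the reads gave 0 for each as well. Among all 10358 genes, called or not, 49 were higher in both at an unadjusted p under 0.05 by edgeR and by limma. At that level 100 were higher in Carm1-KO and lower with EZM2302, 56 went the other way and 109 were lower in both. The chance values given here are for called genes and do not apply to these unadjusted counts, for which none were computed. Trpm2 and Cyp4f16 were named after their values were seen. With the 200 genes of smallest p in each direction, both sets leaned lower in the scaffolds. The median of all genes tested in both was not set beside them. A lean shared by genes expressed in cDC1 thus cannot be told apart from a shift of these sets. The set higher in Carm1-KO had a median of -0.07 (97 of 153 negative, camera adjusted p = 0.0196, but adjusted p = 0.224 with an estimated correlation) and the set lower in Carm1-KO also a median of -0.07 (98 of 164 negative, camera adjusted p = 0.0579, and adjusted p = 0.265 with an estimated correlation).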

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

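Values in the scaffolds were tested for a library that stood apart within its vaccine group, a test planned beforehand. They were those of the named and called genes, which came from the named-gene rule, the levels of the called lists and the read totals. In 102 groups of 4 or 6 libraries, 7 had such a library, and chance gives about 5% of groups. All 7 were groups of gene values, so the share among gene values alone was higher than over all 102. In EZM2302 library 2, Pou2af1 was at 67.8 normalized counts, below 134 to 149 in the other 3. In control library 2, Cxcl5 was at 203.0 (the others 511 to 711), Mmp12 at 638.8 (1449 to 2347) and Sirpb1a, which has near-identical family members, at 2461 (1348 to 1622). In control library 5, Naaa was at 6725, against 10015 to 11931 in the other controls. In control library 1, Ccl22 was at 44.0 (the others 62.4 to 72.9) and Col5a2 at 2326 (2985 to 3460). Control library 2 was thus the one apart for 3 of the 7 genes, and it also had the highest adipocyte level of all 10 libraries (10.9 on the log2 scale).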

How the results depend on the processing

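The fits with thinned counts, the length correction, the adipocyte and globin levels and the libraries left out for them, as well as the lists without a library or with quantile normalization, were chosen after seeing the data. No called gene changed sign under any alternative run in either comparison. Among values of named genes under the alternatives, 959 kept their side of the threshold in cDC1, 145 lost it and 24 gained it, and 1623, 246 and 39 did so in scaffolds. The kept values include those of named genes not called in the main fit, which had no call to lose. The share lost among called genes was therefore higher than these counts give.

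In cDC1, DESeq2 called 151 higher and 110 lower, and leaving out the filter gave 204 and 176. RLE factors, limma-voom, the stricter filter, thinning to the smallest total and the length correction kept the counts within 1.5 times. Leaving out a library gave 4 to 312 higher and 9 to 268 lower. In scaffolds, median centring gave 107 and 60. Leaving out the fat-rich controls gave 273 and 168, leaving out the globin-rich EZM2302 libraries 67 and 58, the adipocyte covariate 391 and 295, and the globin covariate 0 and 0 by limma (1804 at an unadjusted p under 0.05). The correlation of globin level with group was 0.726, so that covariate also takes up part of the group difference. Leaving out a library gave 10 to 386 higher and 2 to 251 lower. Pseudocounts of 0.5 and 10, no filter, quantile normalization and edgeR on the reads stayed within 1.5 times. Fewer libraries or genes were tested in some of these fits; otherwise the cause was not tested.

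For gene lists, an estimated correlation and fry each gave 0 higher and 0 lower lists in cDC1 and 0 and 0 in scaffolds. Leaving out a library gave 1 to 4 higher and 2 to 3 lower lists in cDC1, and 7 to 14 and 3 to 8 in scaffolds. Without the globin-rich EZM2302 libraries 7 lists were higher, and with the globin covariate 4 were higher and 9 lower, where camera ranked the maturation, erythroid and endothelial lists lower without passing (adjusted p = 0.923, 0.838 and 0.728), while their medians shrank and stayed positive (0.07, 0.11 and 0.01). For genes that rose in Carm1-KO, the median in scaffolds was -0.0681 with the 200 genes of smallest p (camera adjusted p = 0.0196, but adjusted p = 0.224 with an estimated correlation), and that of genes that fell was -0.0699 (0.0579, and 0.265).

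With the replicate number as a block, edgeR called 142 higher and 104 lower in cDC1, all 154 genes included. In scaffolds limma then called 167 higher and 53 lower, with 105 of the 264 genes shared and 75.9% higher against 62.5%. Control libraries 5 and 6 share no number with an EZM2302 library, so they added nothing to the vaccine contrast in this block fit. Correlations of same-numbered libraries' deviations were 0.00653, 0.0523 and 0.0136 in cDC1 and 0.406, 0.385, -0.0554 and 0.169 in scaffolds, where 3 of 4 pairs were over 0.1. As a hint from the data, 3 of 6 cDC1 and 4 of 8 numbered scaffold libraries correlated best with their own number. The labels do not say that a number marks a shared animal or day, and not every pair was over 0.1, so the libraries were treated as sharing only a number, and whether some were paired is not settled.

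Many changes of 1.5-fold would be missed at these depths and replicate numbers: on simulated data 7 of 100 such genes were recovered in the scaffold design and 48 of 100 in cDC1. No simulation varied depth or the number of libraries. Averaging with the s libraries, s libraries alone, a correlation model over all libraries and the contrast of plain and s libraries were not run, since the s libraries had no values here, and plain libraries alone is the fit reported.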

Other observations

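The tests of size factors, blood and macrophage share were chosen after the results were seen. For transcript length, the ribosomal class, lung transcripts and other splits, the predictions were recorded as written beforehand. The length correction itself was added after seeing the data, so the length test was not part of the first plan. The patterns that the length, ribosomal and lung tests address were observed in these data. The test of macrophage share was changed from a permutation of genes to an exact permutation of libraries after both values were seen. The genes of the first 2 paragraphs were chosen after their values were seen. They stand as single genes, with no test of a group. In EZM2302 scaffolds, Adamts4, which cleaves proteoglycans, rose from 103 to 363 normalized counts (log2 1.80, SE 0.14, limma adjusted p = 0.000711), the protease inhibitor Timp1 rose from 1071 to 3222 (log2 1.61, limma adjusted p = 0.0158) and the collagen Col12a1 from 2173 to 6745 (log2 1.62, limma adjusted p = 0.0158). Ccn4, Cemip and Ccn1, secreted or matrix-linked proteins, rose by 2.02, 1.67 and 1.35 on the log2 scale (limma adjusted p = 0.0212, 0.0124 and 0.0212). Ptx3, Saa3 and the interleukin-1 receptor Il1r1 rose by 1.52, 0.96 and 0.89 (limma adjusted p = 0.0344, 0.0302 and 0.0158). Myd88 and Tlr1 fell by 0.55 and 0.48 (limma adjusted p = 0.0396 and 0.0321), and Ikzf1, Plcg2, Rasgrp1 and Pik3cd fell by 0.65, 0.66, 0.65 and 0.53 (limma adjusted p = 0.0368, 0.0290, 0.0245 and 0.0473). Of 12 immunoglobulin V genes tested, 12 were positive (median log2 3.35) and limma called 5 higher, where reads shared within the family leave each gene uncertain.

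In Carm1-KO cDC1, 13 mitochondrially encoded genes were tested, of which 10 were negative (median -0.15) and edgeR called 2 lower, ATP8 and ND6 (log2 -0.53, edgeR adjusted p = 0.0496). ATP8 encodes a subunit of ATP synthase. The nuclear genes Cox6c and Uqcrh fell by 0.88 and 0.73 (edgeR adjusted p = 0.0145 and 0.0379). Irf8, a transcription factor that cDC1 need, was at 0.17 (edgeR adjusted p = 0.2999).

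Some ribosomal protein genes and some genes under 1000 bases were among those lower in Carm1-KO cDC1. Of 82 ribosomal protein genes tested, edgeR called 7 lower (Rpl22, Rpl22l1, Rpl26, Rpl29, Rpl32, Rpl34 and Rps15) and 1 higher (Rps2), more lower calls than among other genes (Fisher's exact p = 3.64e-07, across genes, which are not independent). A like fall of the whole class was argued against, since its median was -0.0571 with an SD of 0.35 across genes and 45.1% were positive (camera p = 0.0526, and p = 0.563 with an estimated correlation), so that a fall of part of the class stays open. A length trend was argued against as the whole cause for the 14 lower genes under 1000 bases. They had a median of -0.6434 after a length correction and -0.65 before, with 13 past the threshold after (highest adjusted p = 0.0563, limma). A length was known for 88.3% of called genes. Among these, 14 of 61 lower and 7 of 75 higher genes were under 1000 bases, so short genes were not confined to the lower calls. Of the 7 ribosomal protein genes called lower, only Rpl32 and Rps15 were among these 14, so the length test did not cover the others. All 497 tested genes under 1000 bases had a median of 0.01, against -0.01 in the longer tested genes. Reads shared with processed pseudogenes, and the loss of Carm1 itself, may account for the pattern and were not tested.

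Lung epithelial transcripts were present in all 10 scaffold libraries, and Sftpc and Scgb1a1 were called higher with EZM2302 (from 1096 to 1731 and from 2284 to 3987 normalized counts, limma adjusted p = 0.0398 and 0.0402). Both were at 0 in all 6 cDC1 libraries. All 18 genes of a list of lung markers were in the table, of which Napsa, Hopx, Aqp5 and Muc1 are also expressed in other tissues; the abundant Sftpb went from 403 to 572 and Sftpa1 from 216 to 318 without passing, and no sort or gate is stated. Across the 10 libraries the log2 levels of Sftpc and Scgb1a1 had Pearson's r = 0.9522 (permutation p = 3e-05) and Spearman's rho = 0.952 (permutation p = 1e-04). Pearson's r was 0.909 without the 2 farthest libraries and 0.816 within groups. Both genes were higher with EZM2302 and the permutations ignored the groups, so these p-values partly reflect that shared difference. The value within groups was not tested, and no other pair of lung genes was correlated. Lung RNA or lung reads in varying amounts would give such values, which do not prove that source. The size factors were argued against, as 2 of 2 genes separated the groups in reads scaled to the library total too, and whether tissue, a carried-over library or the treatment is the source stays open.

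B cell and plasma cell, neutrophil and erythroid lists ranked higher in EZM2302 scaffolds by camera (but adjusted p = 0.416, 0.697 and 0.622 with an estimated correlation, with 0, 1 and 0 members called by limma and 8, 13 and 5 at an unadjusted p under 0.05; 0, 1 and 4 called by edgeR on the reads), and 2 of these 4 libraries were rich in globin. With the globin level as a covariate, 17.0% of the B cell list's median was kept (1.38 with a median SE of 0.60 before, 0.23 with 0.79 after, and 0.21 without the 2 globin-rich libraries) and 76.21% of the neutrophil list's. Both lower-globin EZM2302 libraries, 1 and 2, lay above all controls for the B cell list (7.13 and 7.004 against at most 6.54). Their globin levels, 9.56 and 9.46 on the log2 scale, were themselves close to the highest control (9.53), so this does not argue against more blood. More blood in the EZM2302 scaffolds cannot be told apart from the vaccine's effect for either list, since the globin level correlated with the group (0.726). A lower share of macrophages that would raise every other cell type alike was argued against. B cell and T cell lists moved apart by 1.747 (exact permutation p = 0.0190 over 210 splits of the libraries, two-sided). The T cell median was -0.32 (camera adjusted p = 0.419), and the difference of both levels overlapped between groups (-0.147 to 2.12 in controls, 1.36 to 2.96 with EZM2302). A lower share of macrophages together with other changes was not tested. Of 20 monocyte and macrophage markers, 9 were positive and 11 negative (median -0.02). A larger number of B cells or neutrophils with EZM2302 may also account for the higher lists and was not tested.

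For the cDC1 comparison, the 10 splits of 6 libraries are too few for a share under 0.05; the real split gave 154 genes and the highest other 0. For the scaffolds, 1 of 100 splits drawn, the real one, gave 264 genes and the highest other gave 7. A chance assignment to groups is unlikely at that share, though not excluded. The splits cannot tell the vaccine from any other difference between the groups.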
